A study of Mus musculus with 4 samples.

How the data were processed

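RNA sequencing was done on total RNA of TBV2 cells, a mouse embryonic stem (ES) cell line, extracted with TRIzol and made into Illumina libraries, per the labels' protocols. The 4 libraries were 1 from a non-targeting control (NT) and 3 from separate clones in which T-UCstem1, an ultraconserved long noncoding RNA also labelled uc.170, was knocked down (KD). Cells were grown in serum with LIF, and the series description adds feeder cells and high density.

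Reads were processed with TopHat, Cufflinks and Cuffdiff on the mouse build mm9, per the submitters' processing notes. Versions, alignment options, gene annotation and the scaling between libraries are not given in the sources used here. The deposited table holds 1 FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) per gene for a condition named treated and 1 for a condition named control, per the file headers. Control was taken as the NT library and treated as the 3 KD clones pooled by the authors, since KD is the other condition in the labels. Values per clone were not analysed here, so no SD, standard error or n accompanies an FPKM.

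The deposited p-value and q-value of each gene are those of Cuffdiff, per the file headers, and the authors marked genes that passed their threshold. The deposited q was reproduced by Benjamini-Hochberg adjustment over the 15477 tested rows to within 5.2e-07. The largest q among the 178 marked genes was 0.0478. The smallest p was 5e-05, shared by 95 tested rows, so ranks among those rows have no finer order. With 1 control library, the deposited p-values contain no measured spread between control cultures.

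The table had 27542 rows, of which 12055 were not tested by the authors, 9 failed and 1 exceeded Cuffdiff's depth limit. No gene symbol was given in 3830 rows and 463 rows carried several symbols. Reads of overlapping or near-identical genes may have been merged or split in such rows, and a use of strand is not stated. Symbols that a spreadsheet had turned into dates stood in 25 rows and were left as they were. The log2 column of the deposited table gives control over treated, and 1801 of its cells held a spreadsheet error in place of an infinite value, each with a control FPKM of 0. Of the 20524 finite cells, 7 differed from the recomputed ratio by more than 0.001. Fold changes were therefore recomputed as log2((KD FPKM + 1)/(NT FPKM + 1)), so that positive values are higher in the KD. The pseudocount of 1 understates the change of genes with low FPKM. Rows at 0 FPKM numbered 5209 in the KD and 6809 in the control. A value of 0 can be a failed estimate, so such genes are described as listed at 0 and no ratio is given for them.

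The number of reads per library is not stated. In transcripts of at least 1500 bp the most frequent low value of FPKM times length in kb was 0.033 in the control, taken over 214 genes. If that is the worth of 1 fragment, 3 fragments on a 2 kb transcript in the control would be about 0.0495 FPKM. The pooled KD value gave no depth per clone. These figures cover counting error only.

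Before the data were examined, 36 gene lists, the rule for named genes and the alternative settings were fixed. A list median was the median log2 fold of members with at least 1 FPKM in either group. It was placed among the medians of 10000 random lists of the same size matched on mean FPKM in 20 bins, and lists with fewer than 5 such members were not placed. The percentile describes these libraries and is not a test across replicates. A list median between the 2.5 and 97.5 percentiles is described as within the range of random lists. Members were counted as having risen or fallen by the authors' mark, and again with Benjamini-Hochberg adjustment of the deposited p over the list alone at 0.05. Chromosome medians were placed in the same way. No test of differential expression was run on the FPKM, because each condition has 1 value.

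The named genes were the 10 largest rises and 10 largest falls among marked genes with 1 symbol and at least 5 FPKM in the higher group, leaving out predicted and small RNA genes. To these were added up to 4 marked members with the largest change and up to 2 unmarked members with the highest mean FPKM of each list, and 25 fixed genes. Other genes named in the text were chosen after their values were seen. These are Spp1, Lama1, Sparc, Uty, Amn, Zscan4e, Col1a1, Col1a2, Col3a1, Ddit4, Ccng1, Mdm2, Cdk1, Tcl1, Ldha, Pgk1, Ctsl, Pth1r, Peg10, Mirg, Abi2, Rpl37a, Serpinh1, Slc2a3, Nr0b1, Tfcp2l1, Klf2, Uba1y, Kdm5d, Kdm6a, Kdm6b, Tuba3b and the called annexins. Of the named genes, 1 is not reported here.

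List scoring was tested on simulated data over 12330 genes. All 10 lists of 20 genes shifted by 1 on the log2 scale were recovered, and 7 of 200 unchanged lists (3.5%) fell outside the range of random lists. The simulated noise was independent between genes, with an SD of 0.5. The simulation therefore checks the scoring code only. It does not cover smaller shifts or lists whose members vary together. Alternative settings were a q of 0.01, a minimum log2 fold of 1, other FPKM minimums, recomputed and Bonferroni adjustment, other pseudocounts, scaling to the median of expressed genes or of housekeeping genes, rows with 1 symbol only, and lists without members shared with another list. Leaving out genes of chromosomes 6, 10 and Y, leaving out genes in shifted segments, leaving out genes at 0 FPKM and subtracting the median of each gene's chromosome were added after the data were seen. GC content and transcript length came by gene symbol from GENCODE vM21, which is on another build, so none of its coordinates were used. Coordinates are mm9, counted from 1, from the deposited table. T-UCstem1 itself was not analysed here, because no gene symbol was matched to it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.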

Results

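Gene expression was profiled by RNA sequencing in mouse TBV2 ES cells carrying a non-targeting control or a knockdown of T-UCstem1, a long noncoding RNA that contains an ultraconserved element. The control was 1 library and the KD was 3 clones, which the authors combined into 1 FPKM per gene. There are no replicate values for either condition, and the level of T-UCstem1 in these libraries was not analysed here. Of 27542 genes and transcribed loci, 15477 were tested in the authors' deposited table and 13470 reached 1 FPKM in either condition. Across 12330 named genes at that level the log2 values of KD and control had a Pearson r of 0.967, where genes are not independent replicates. Their median log2 fold was 0.022, with quartiles of -0.16 and 0.22.

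The comparison asks how the ES cell transcriptome differs when T-UCstem1 is lowered, with self-renewal and proliferation as the subject named by the study's title. KD cells had higher levels of basement membrane and extraembryonic endoderm genes, and of mesenchymal genes and feeder fibroblast markers. Zscan4 genes of the early embryo and germ-line genes were also higher. In the 2-cell-like and germ-line lists, 2 of 12 and 4 of 18 tested members were called higher. Several genes of glycolysis and the hypoxia response were lower, while the pluripotency genes Pou5f1, Sox2 and Nanog were not called. By the authors' deposited table, 149 genes rose in the KD and 29 fell, so that 83.7% of the 178 calls were higher. Genes that rose were mostly low in the control, with a median of 1.93 FPKM against 13.1 FPKM in the KD. Genes that fell had a median of 62.3 FPKM in the control and 27.1 FPKM in the KD.

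The largest rise was that of Dppa2, a chromatin protein of pluripotent and germ cells (chromosome 16, 48303804 to 48319626), at 38.6 FPKM in the KD and 0.766 FPKM in the control. Its log2 fold was 4.49, with a q of 0.00815 in the authors' deposited table. With 1 control library, a low level of Dppa2 particular to that library cannot be told apart from a rise through the knockdown. Eif2s3y and Ddx3y, Y-linked genes for a translation initiation factor subunit and an RNA helicase, followed with log2 folds of 4.46 and 3.51. Syce1, a component of the meiotic synaptonemal complex, had a log2 fold of 3.25. The basement membrane genes Col4a1 and Col4a2, which lie next to each other on chromosome 8 (11198423 to 11449287), rose from 10.9 to 109 FPKM and from 6.06 to 63.0 FPKM. Lamb1, a laminin chain of the same sheet, rose from 11.3 to 96.5 FPKM. Srgn, a granule proteoglycan, and Cubn, an endocytic receptor of visceral endoderm, had log2 folds of 3.10 and 2.95. Zscan4f, a telomere-associated gene of the 2-cell embryo, was listed at 0 in the control and at 6.77 FPKM in the KD. Spp1, the secreted phosphoprotein osteopontin, was the most abundant of the genes named here that rose, at 956 FPKM against 194 FPKM.

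Among the genes that fell, Egln3, an oxygen-sensing prolyl hydroxylase, changed most, from 18.1 FPKM in the control to 3.73 FPKM in the KD. It fell by 2.01 on the log2 scale, with a q of 0.00815 in the authors' deposited table. Ifitm1, an interferon-inducible membrane protein, fell to 0.348 of its control level of 152 FPKM, and Fzd7, a Wnt receptor, fell from 37.5 to 14.4 FPKM. Slc2a1, the glucose transporter GLUT1, fell from 215 to 94.1 FPKM and Bnip3, a mitophagy receptor, from 62.3 to 27.1 FPKM. Pfkl, a phosphofructokinase of glycolysis, fell from 112 to 50.1 FPKM. Tuba3a, Zfp229, Btnl4 and Arl14epl completed the 10 largest falls, between -1.29 and -1.17 on the log2 scale. Reads of Tuba3a may be shared with its near-identical copy Tuba3b.

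**Figure D1:**
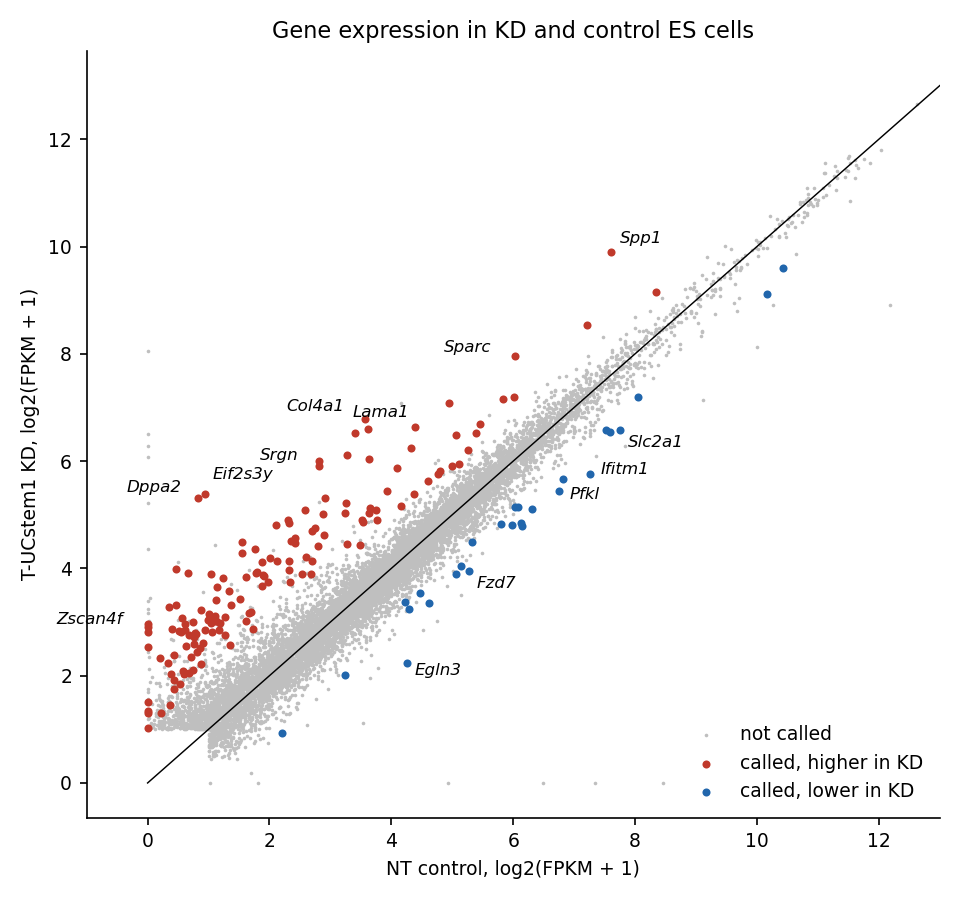
Expression in the control (horizontal axis) and in the T-UCstem1 KD (vertical axis), as log2(FPKM + 1), for 12330 named genes with at least 1 FPKM in either condition. Each point is 1 gene and the line marks equal values. Genes called higher (red) lie mostly toward the low end of the control axis, as Dppa2 does at 0.766 FPKM, and genes called lower (blue) at higher levels, as Slc2a1 does at 215 FPKM.

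Primitive and visceral endoderm, the extraembryonic lineages that line the yolk sac, gave the clearest group. Of 23 tested members 14 rose, none fell and 9 did not pass the test. Adjusted over the list alone 22 rose. The 22 expressed members had a median log2 fold of 1.96, at percentile 100 of random lists. The lineage transcription factors Gata6 (9.67 against 1.18 FPKM), Gata4 (16.7 against 3.37 FPKM), Sox17 (4.89 against 0.551 FPKM) and Sox7 (8.13 against 2.23 FPKM) rose together with the matrix genes. Lama1 rose from 19.9 to 98.5 FPKM and Sparc, a collagen-binding matrix protein, from 64.2 to 249 FPKM. Lamc1, the most abundant laminin chain of the list, stood at 172 FPKM against 93.1 FPKM and did not pass, with a q of 0.234 in the authors' deposited table. Amn, the partner of Cubn in endocytosis, was at 7.09 FPKM against 0.601 FPKM and was not called. Markers of feeder fibroblasts moved in the same direction, with a list median of 1.03, and the fibrillar collagen genes Col1a1 and Col1a2 were at 3.63 and 4.03 FPKM in the KD against 0.920 and 1.12 FPKM. Col3a1, another fibrillar collagen gene, was higher by only 0.181 FPKM.

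Mesenchymal genes were also higher. In the list of mesenchyme and epithelial-to-mesenchymal transition 9 of 19 tested members rose, none fell and 10 did not pass, and adjusted over the list alone 10 rose. The median was 1.28, at percentile 100. S100a4 and S100a6, calcium-binding proteins of motile cells, rose from 8.70 to 68.6 FPKM and from 29.7 to 135 FPKM. Acta2, smooth muscle actin, rose from 0.535 to 6.80 FPKM and Cav1, the coat protein of caveolae, from 0.459 to 6.01 FPKM. Fn1, fibronectin, and Snai1, a repressor of epithelial genes, did not pass, at 221 against 256 FPKM and 5.35 against 5.92 FPKM. Of 21 tested feeder fibroblast markers 4 rose, none fell and 17 did not pass. Adjusted over the list alone 12 rose and 1 fell. Tnc (2.66 to 16.3 FPKM), Bgn (2.05 to 13.3 FPKM), Fbln2 (2.48 to 14.3 FPKM) and the chemokine Ccl2 (8.60 to 36.5 FPKM) were those called, with a list median at percentile 100. Without an FPKM minimum the median was 0.57 at percentile 100.

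Epithelial and trophectoderm genes shifted less. The keratins Krt18 (2.43 to 14.0 FPKM) and Krt8 (5.08 to 17.5 FPKM), shared by both lists, were the 2 members called in each. The trophectoderm list had a median of 0.54 at percentile 99.8, and of 0.23, also above the range of random lists, without an FPKM minimum. Of its 11 tested members 9 were not called, and adjusted over the list alone 3 rose. Among its expressed members 9 lay above 0 and 2 below. Tead4 was at 12.3 against 10.1 FPKM and Tfap2c at 16.5 against 21.2 FPKM, neither of them called. The epithelial adhesion list had a median of 0.31 at percentile 100, with 19 of 21 not called, and adjusted over the list alone 3 rose. Cdh1, E-cadherin, was at 78.0 FPKM against 52.7 FPKM and was not called.

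**Figure D2:**
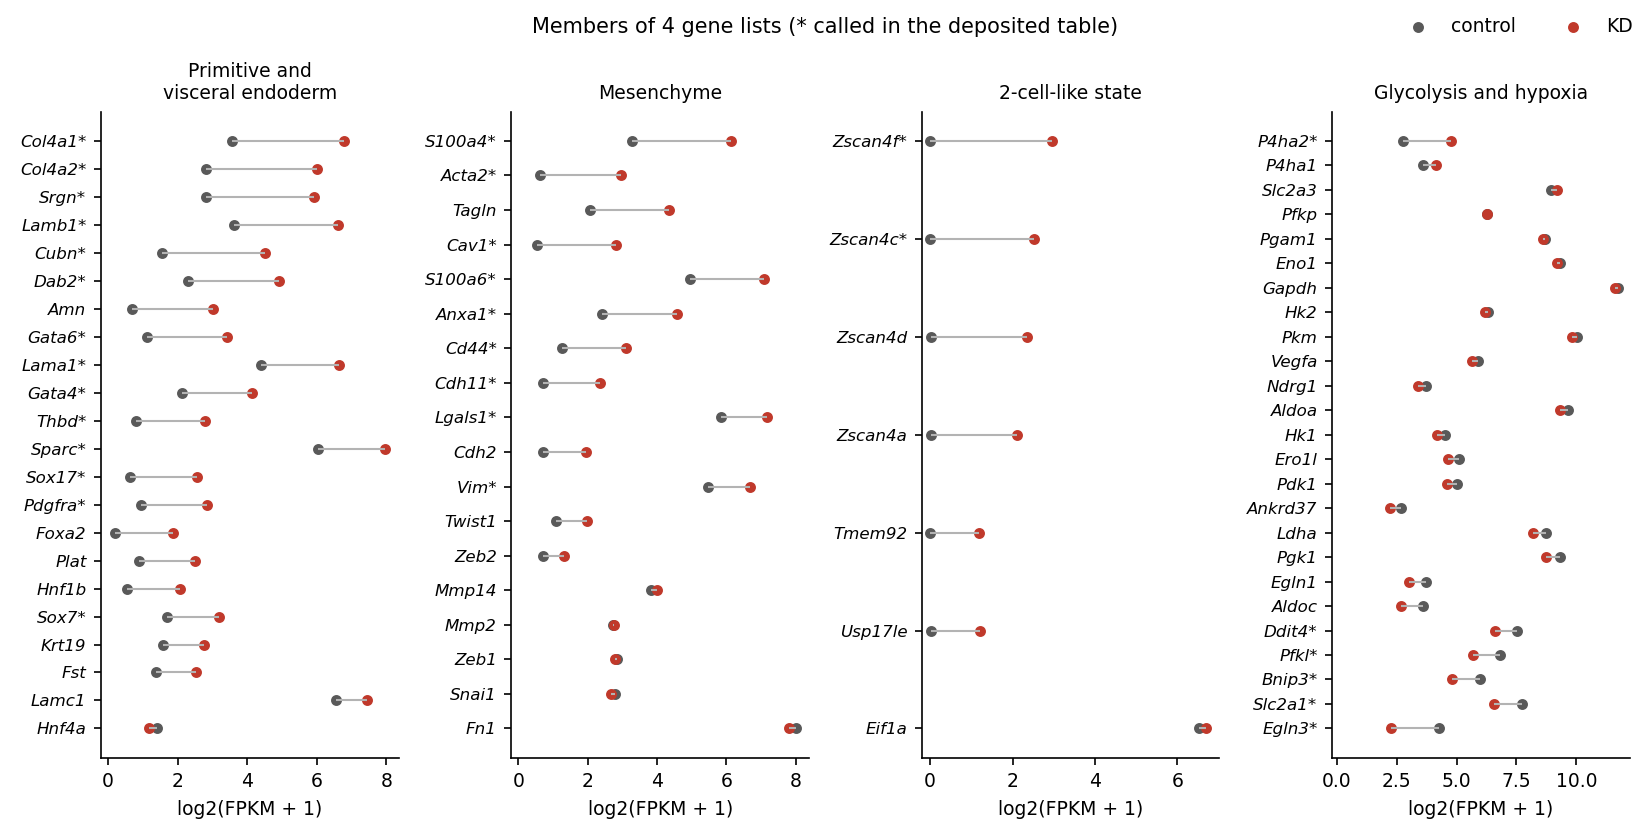
Levels of the members of 4 gene lists in the control (grey) and the T-UCstem1 KD (red), on a horizontal axis of log2(FPKM + 1), with 1 line per gene and an asterisk for genes called in the authors' deposited table. Most endoderm and mesenchyme members lie to the right in the KD, such as Col4a1 at 109 FPKM against 10.9 FPKM, while glycolysis and hypoxia members such as Slc2a1 lie to the left.

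Few pluripotency genes were called. None of the 22 naive pluripotency genes was called, and their median was 0.029 at percentile 51.5; adjusted over the list alone 1 fell. Nanog was at 489 FPKM against 434 FPKM, Klf4 at 132 against 115 FPKM, Zfp42 at 572 against 511 FPKM and Esrrb at 211 against 240 FPKM. With members on chromosomes 6, 10 and Y left out, a setting chosen after the data were seen, the naive median was -0.18, below the range of random lists. Tcl1, an AKT cofactor of naive cells, was at 59.9 FPKM against 106 FPKM, Nr0b1 at 101 against 153 FPKM, Klf5 at 105 against 152 FPKM, Tfcp2l1 at 99.1 against 143 FPKM and Klf2 at 80.4 against 111 FPKM, none of them called. In the core list of 12 genes Dppa2 rose, Sall1, a zinc-finger partner of NuRD, fell from 64.0 to 34.2 FPKM, and 10 did not pass. The counts were the same adjusted over the list alone, and the median was -0.057 at percentile 16.1. Pou5f1, which encodes OCT4, was at 1078 FPKM against 1036 FPKM with a q of 0.999 in the authors' deposited table, and Sox2 at 216 against 257 FPKM.

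Markers of later embryonic lineages were mostly low. The 14 tested formative and primed epiblast genes were not called and had a median of 0.014 at percentile 41.1, and adjusted over the list alone 1 rose. Dnmt3b was at 25.6 against 16.5 FPKM and Fgf5 at 0.450 against 0.129 FPKM. None of 8 tested mesendoderm and mesoderm genes was called (median 0.28, percentile 90.6), and adjusted over the list alone 1 rose. T, brachyury, was at 0.323 against 0.133 FPKM. Of 16 tested neural genes 1 rose, the intermediate filament gene Nes (0.991 to 7.17 FPKM), and 15 did not pass. The neural median was 0.37 at percentile 99.5, but 0.071 and within the range of random lists without an FPKM minimum, and adjusted over the list alone 4 rose. Sox1 was at 2.03 against 3.58 FPKM, Pax6 at 0.906 against 0.307 FPKM and Tubb3 at 47.3 against 36.2 FPKM. Cdx2 was listed at 0 in the control and at 0.189 FPKM in the KD. The macrophage and blood list had no calls among 6 tested members, with a median of 0.081 at percentile 60.6, and adjusted over the list alone 1 rose.

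Among genes of the 2-cell-like state, a rare condition of ES cells that resembles the 2-cell embryo, the Zscan4 genes were listed at or near 0 in the control, whereas the translation factor gene Eif1a was at 91.2 FPKM against 102 FPKM in the KD. Of 12 tested members 2 rose and 10 did not pass, and adjusted over the list alone 3 rose. The 2 that rose, Zscan4c and Zscan4f, were listed at 0 in the control. Of the 178 called genes 12 were listed at 0 there, these 2 among them. The 7 expressed members, of which 1 reached 1 FPKM in the control, had a median of 2.10 at percentile 100, and without an FPKM minimum all 17 members had a median of 0.75 at percentile 100. Zscan4c was listed at 0 against 4.77 FPKM, while Zscan4d was at 4.09 FPKM against 0.0146 FPKM and was not called. Zscan4e, a called gene outside the list, was listed at 0 against 1.84 FPKM. These paralogs are nearly identical in sequence, so the share of each is uncertain. Most of the 7 expressed members are Zscan4 paralogs, so the list median largely reflects that gene family. Random lists hold mostly unrelated genes, so the percentile does not show that separate genes of this state rose.

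Germ-line genes were higher as a group. Of 18 tested members 4 rose, 1 fell and 13 did not pass, and adjusted over the list alone 8 rose and 1 fell. The median was 1.02 at percentile 100. Rpl10l, a testis ribosomal protein, rose from 3.29 to 27.2 FPKM, and Ddx4, the germ-cell helicase VASA, from 0.436 to 6.16 FPKM. Stra8, a retinoic acid target that starts meiosis, rose from 32.3 to 88.9 FPKM, and Taf7l from 1.25 to 6.25 FPKM. Tuba3a was the member that fell. Tuba3a and Stra8 both lie on chromosome 6, whose genes were higher in general.

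Polycomb genes themselves were not called. The list of 25 genes, which holds subunits of Polycomb repressive complexes and the opposing demethylases Kdm6a and Kdm6b, had a median of 0.10 at percentile 87.4, with no call over all genes or adjusted over the list alone. Ezh2, the methyltransferase, was at 84.1 against 58.6 FPKM, with a q of 0.371 in the authors' deposited table. Eed was at 124 against 101 FPKM and Suz12 at 93.9 against 100.4 FPKM. Among 33 tested developmental regulators with bivalent chromatin in ES cells 4 rose and 29 did not pass, and adjusted over the list alone 9 rose. The 4 were Gata6, Gata4, Sox17 and Sox7, which the endoderm list also holds. The median of the 22 expressed regulators was 0.70 at percentile 100, and 0.37 at percentile 92.5 without genes of other lists. Over all 95 regulators, of which 15 reached 1 FPKM in the control, the median was 0.18 at percentile 100. None of 15 genes of DNA methylation and demethylation was called over all genes or adjusted over the list alone, with a median of -0.00043 at percentile 39.5. Dnmt3l, a cofactor of de novo methylation, was at 168 against 250 FPKM.

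Cell-cycle genes differed little. Among 32 G1/S genes 1 rose, Ccnd2, cyclin D2, on chromosome 6 (1.17 to 7.12 FPKM), and 31 did not pass. Adjusted over the list alone 2 rose and 1 fell. The median was -0.094 at percentile 1.82, and within the range of random lists without genes of other lists. None of 27 G2/M genes was called, and adjusted over the list alone 1 fell. Their median was -0.10 at percentile 1.06, and the mitotic kinase Cdk1 was at 86.1 against 140 FPKM. Ccnd1 was at 36.7 against 20.9 FPKM and Pcna at 222 against 219 FPKM. None of 15 CDK inhibitor and senescence genes was called over all genes or adjusted over the list alone, with a median of 0.12 at percentile 81.1. Cdkn1a, which encodes the inhibitor p21, was at 40.7 against 27.8 FPKM with a q of 0.582 in the authors' deposited table, and Cdkn1b at 55.9 against 71.5 FPKM.

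Targets of p53, the DNA damage response factor, were slightly higher as a group. Of 24 tested targets 1 rose, the polo-like kinase gene Plk2 (8.63 to 21.0 FPKM), and 23 did not pass. Adjusted over the list alone 6 rose. The median was 0.37 at percentile 100, and 19 of 23 expressed members lay above 0. Mdm2 was at 72.2 against 43.8 FPKM, Ccng1 at 108 against 63.6 FPKM and Trp53 itself at 203 against 177 FPKM. In the apoptosis list Cycs, cytochrome c, rose from 31.1 to 59.1 FPKM and 20 of 21 tested members did not pass. Its median was -0.044 at percentile 21.5, and adjusted over the list alone 1 rose. Cycs lies on chromosome 6.

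Growth-related lists moved in small steps. None of 28 Myc target and ribosome biogenesis genes was called over all genes or adjusted over the list alone, with a median of 0.20 at percentile 99.9. Nucleolin, Ncl, was at 1036 against 707 FPKM and Myc at 9.27 against 5.92 FPKM. The 39 cytosolic ribosomal protein genes had no call over all genes or adjusted over the list alone, with a median of -0.099 at percentile 1.02. The 22 tested histone genes were not called, nor was any adjusted over the list alone, with a median of 0.23 at percentile 90.5. The 19 housekeeping genes had no call over all genes or adjusted over the list alone and a median of 0.038 at percentile 58.8. Of 23 LIN28 and let-7 targets Thbs1, thrombospondin, rose from 0.702 to 5.02 FPKM and 22 did not pass. Their median was 0.048 at percentile 73.2, and adjusted over the list alone 3 rose and 1 fell. Lin28a was at 69.6 against 67.6 FPKM and Lin28b at 5.46 against 7.07 FPKM. Mitochondrially encoded transcripts were not measured, as the mitochondrial row was not tested and was listed at 0.

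Glycolysis and hypoxia genes were lower as a group. Of 26 tested members 5 fell, 1 rose and 20 did not pass, and adjusted over the list alone 6 fell and 1 rose. The median of 25 expressed members was -0.35, at percentile 0. Egln3, Slc2a1, Bnip3, Pfkl and Ddit4, an mTOR inhibitor induced by hypoxia (183 to 95.3 FPKM), were those that fell. P4ha2, a collagen prolyl hydroxylase, rose from 5.73 to 25.9 FPKM. Slc2a3, a more abundant glucose transporter than Slc2a1, was not called, at 591 against 496 FPKM. The abundant enzymes were not called: Ldha was at 289 against 426 FPKM, Pgk1 at 426 against 632 FPKM and Gapdh at 3155 against 3462 FPKM. Pfkl lies in a part of chromosome 10 whose genes were lower in general and Ddit4 outside that part, and without chromosomes 6, 10 and Y 3 members fell.

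Other metabolic and stress lists held few calls. In cholesterol and lipid synthesis Scd2, a fatty acid desaturase, fell from 66.8 to 34.4 FPKM and 22 of 23 tested members did not pass. The median was -0.13 at percentile 3.20, and adjusted over the list alone 1 fell. In the amino acid and ER stress response Pdia4, an ER chaperone gene on chromosome 6, rose from 33.6 to 60.8 FPKM and 24 did not pass. Adjusted over the list alone 3 rose, with a median of 0.12 at percentile 96.6. Of 19 tested interferon response genes Ifitm1 fell and 18 did not pass, with a median of -0.041 at percentile 22.3 and 1 fall adjusted over the list alone.

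Signalling lists showed single targets. In the Nodal, BMP and TGF-beta list 3 of 24 tested members rose and 21 did not pass, and adjusted over the list alone 5 rose. Among the called genes were Ctgf, a matricellular growth factor (3.97 to 16.7 FPKM), and Inhba, an activin subunit (0.809 to 4.69 FPKM). The median was 0.050 at percentile 61.2, and Nodal was at 50.4 against 48.8 FPKM. In the FGF and ERK list Dusp4, an ERK phosphatase, rose from 4.08 to 12.4 FPKM and 21 of 22 did not pass. Its median was -0.083 at percentile 6.47, and adjusted over the list alone 4 rose and 1 fell. In the Wnt list Fzd7 fell and 15 of 16 did not pass, with a median of 0.052 at percentile 61.0, and adjusted over the list alone 3 rose and 2 fell. None of 16 LIF and STAT3 genes was called (median -0.10, percentile 6.64), and adjusted over the list alone 1 fell.

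Imprinted genes went both ways. Of 27 tested members 3 rose, 2 fell and 22 did not pass, and adjusted over the list alone 3 rose and 3 fell. H19 and Igf2, neighbours on chromosome 7, rose from 1.57 to 8.94 FPKM and from 0.874 to 5.08 FPKM, and Peg10 from 23.2 to 48.5 FPKM. Meg3 and Rian, noncoding RNAs of the Dlk1-Dio3 cluster on chromosome 12 (110779206 to 110899921), fell from 69.9 to 26.8 FPKM and from 78.1 to 33.5 FPKM. Mirg, of the same cluster, was at 3.81 against 10.3 FPKM and was not called. The rows of Meg3 and Rian carry further gene symbols, so reads of overlapping genes are included. The list median was 0.23 at percentile 99.9.

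**Figure D3:**
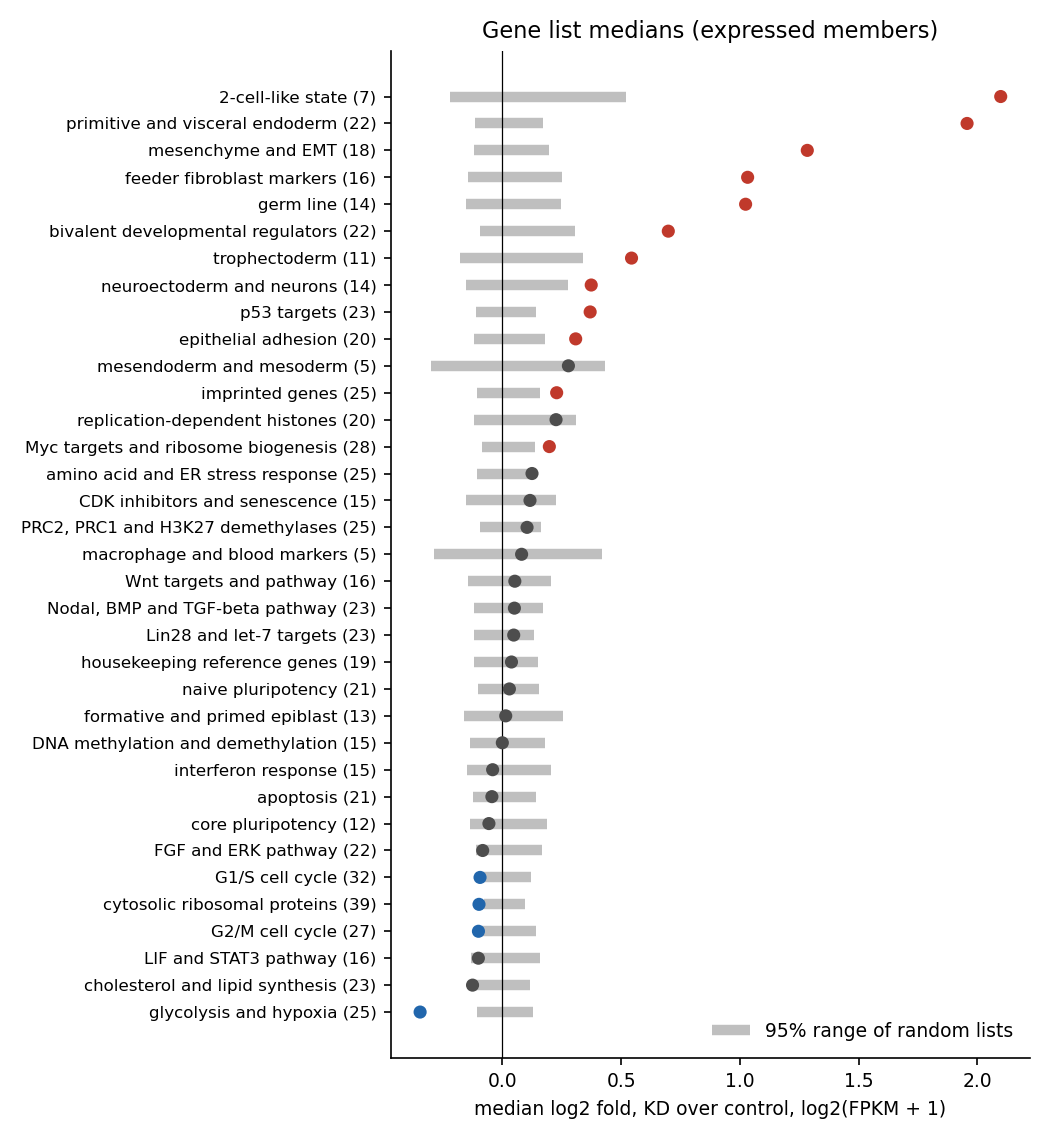
Median log2 fold (KD over control, on log2(FPKM + 1)) of each gene list, with the number of expressed members in parentheses; grey bars span the central range of 10000 matched random lists, all but the outer 2.5% on each side. Points outside it are red when higher and blue when lower. The 2-cell-like list, whose expressed members are mostly Zscan4 paralogs, has a median of 2.10. The endoderm list has a median of 1.96, and the glycolysis and hypoxia list of -0.35.

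Expression also differed by chromosome. The 566 expressed genes of chromosome 6 had a median log2 fold of 0.26 at percentile 100, with 81.1% of genes above 0. The 598 genes of chromosome 10 had a median of -0.16 at percentile 0, and chromosome X a median of 0.11 at percentile 100. Nanog, Ezh2, Gapdh and Cdkn1b lie on chromosome 6, as do the called genes Stra8, Peg10, Cav1 and Fbln2. On chromosome 10 the genes between 69.9 and 95.5 Mb, Dnmt3l and Pfkl among them, had a median of -0.49. Lin28b lies on chromosome 10 but outside that part. On chromosome 1 the 85 genes between 58.9 and 75.4 Mb, Fzd7 among them, had a median of -0.45. The 3 expressed Y-linked genes Eif2s3y, Ddx3y and Uty stood in the control at 2.22%, 2.60% and 3.16% of their KD levels. The medians of the other chromosomes lay between -0.022 and 0.070, of which 7 (chromosomes 2, 5, 7, 9, 12, 13 and 15) also lay outside the range of random sets, so leaving that range was common. Without the genes of chromosomes 6, 10 and Y, a setting added after the data were seen, 128 genes rose and 23 fell.

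**Figure D4:**
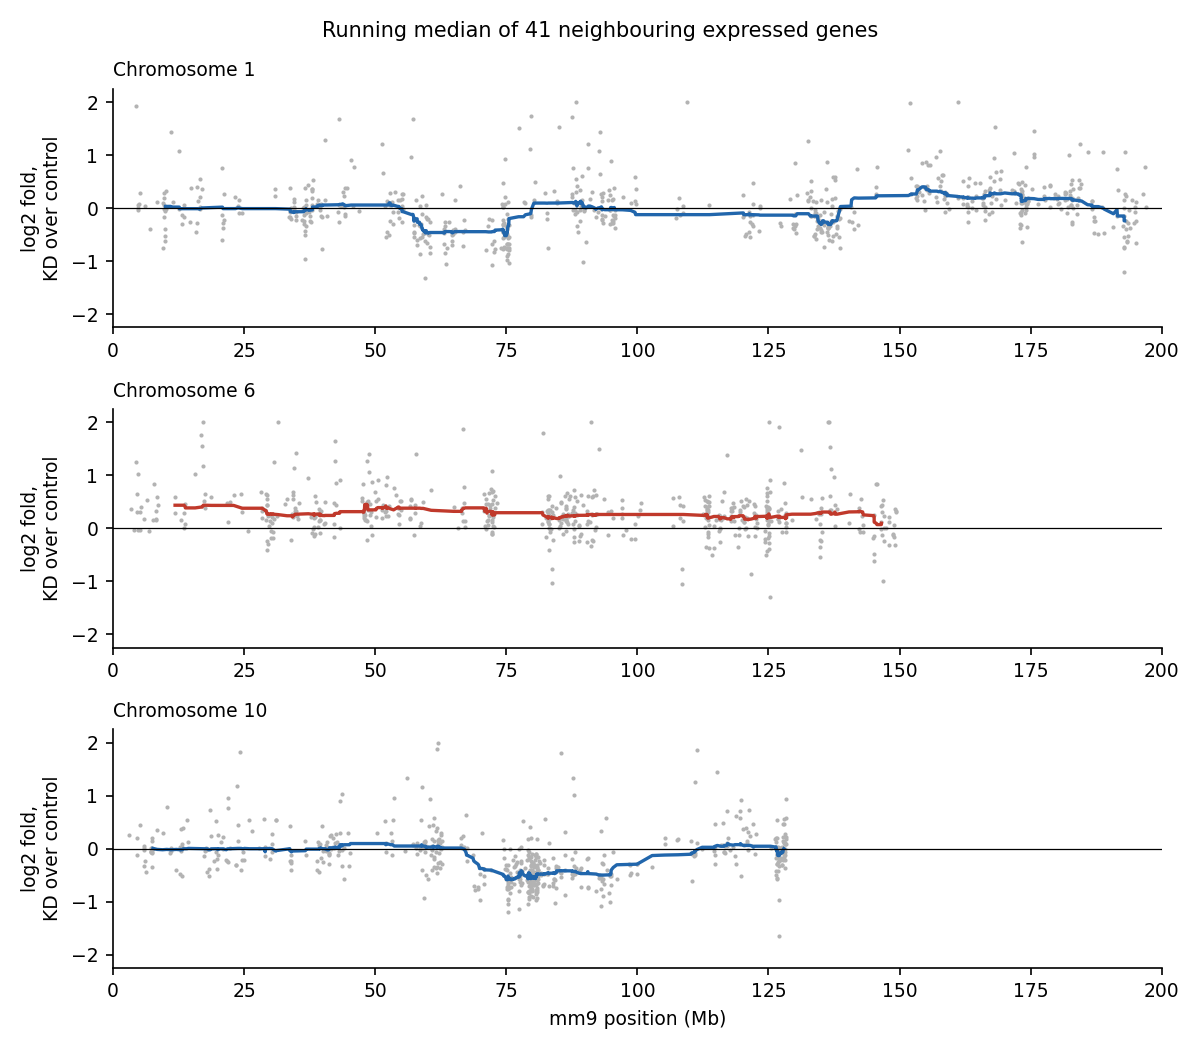
Log2 fold (KD over control, on log2(FPKM + 1)) of expressed genes along chromosomes 1, 6 and 10 against mm9 position in Mb. Grey points are genes, drawn at 2 or -2 when beyond, and lines are running medians of 41 genes. The line of chromosome 6 stays above 0 throughout, and that of chromosome 10 drops to -0.59 near 75.1 Mb.

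The calls rest on the authors' model, and with 1 control library a difference between conditions has no replicate check in the control. By the authors' deposited table, 81 genes rose and 14 fell at a q of 0.01.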

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

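Leaving out chromosomes 6, 10 and Y, leaving out shifted segments, leaving out genes at 0 FPKM and subtracting chromosome medians were tests chosen only after the results were seen. No paired analysis was possible because the deposited table holds 1 value per condition, and leaving out each clone in turn was not possible for the same reason. No called value changed direction in any setting run. The counts of 149 rises and 29 falls ranged from 128 to 162 and from 20 to 30, except at a q of 0.01 (81 and 14) and with Bonferroni adjustment (0 and 0), where the smallest deposited p times the number of tests exceeds 0.05 by construction. Of the named genes, 21 had a q between 0.01 and 0.05 in the authors' deposited table.

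Of the list medians, 332 recomputed values kept their side of the range of random lists, 4 came within it and 6 left it. Neural genes without an FPKM minimum (0.071), bivalent regulators without shared members (0.37) and G1/S genes without shared members (-0.093) or with chromosome medians subtracted (-0.097) came within it. Those that left it were naive pluripotency genes with chromosome medians subtracted (-0.16) or without chromosomes 6, 10 and Y (-0.18), cholesterol genes at a pseudocount of 0.1 (-0.14), and at a minimum of 5 FPKM the FGF (-0.17), interferon (-0.21) and histone (0.82) lists. At that minimum chromosomes 1 (-0.0303) and 11 (0.040) also left the range, and chromosomes 15 (0.036) and 9 (-0.013) entered it. Chromosome 15 entered it at a pseudocount of 0.1 as well (0.053). The cause was not tested for any of these.

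Counts of called members moved most when adjusted over the list alone, where fewer genes are tested. Rises were then 22 in endoderm, 12 in feeder markers, 9 in bivalent regulators, 8 in germ line, 6 in p53 targets, 5 in Nodal, BMP and TGF-beta, 4 each in FGF and neural genes, 3 each in LIN28 targets, Wnt and ER stress, 2 in G1/S, and 1 each in epiblast, mesendoderm and macrophage genes. Falls were 2 in Wnt and 1 each in FGF, G1/S, G2/M, LIF, LIN28 targets, feeder markers and naive pluripotency. Smaller relative moves were to 10 rises in mesenchyme, 3 each in trophectoderm, epithelial and 2-cell-like genes, 6 falls in glycolysis and 3 in imprinted genes, and the other counts stayed as they were. At a q of 0.01 the rises were 1 each in bivalent regulators, imprinted genes and the Nodal list and 0 in ER stress, apoptosis, epithelial, p53 and trophectoderm genes, with 3 falls in glycolysis and 0 in core pluripotency. With a minimum log2 fold of 1 there were 0 rises in apoptosis and ER stress and 0 falls in cholesterol synthesis and core pluripotency, which ended the only calls of the first 3 lists and the fall of Sall1. Without chromosomes 6, 10 and Y there were 0 rises in G1/S, ER stress and apoptosis, 0 falls in germ line and 3 in glycolysis.

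With fewer than 5 members left, no value was obtained for the 2-cell-like list without a pseudocount, at 5 FPKM or without genes at 0 in the control, for the trophectoderm, mesendoderm, bivalent and macrophage lists at 5 FPKM, or for mesendoderm without shared members. Depth per clone is unknown, and control values below about 0.0495 FPKM, near 3 fragments on a 2 kb transcript, have no resolved level.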

Other observations

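The tests of feeder cells over all endoderm and all mesenchyme genes, on the single control library, on the Y-linked genes and on the segment of chromosome 10 were chosen only after the results were seen, as were the gene family and segments given here. A test of feeder cells planned before the results, on the 9 called mesenchyme genes, gave a ratio of 0.149 (median gain 18.3 FPKM), past its bound against feeder cells, and was set aside because called genes are selected for a rise. The test planned for the endoderm list is kept for the 5 basement membrane genes it measures. Of the 178 called genes 116 belonged to none of the lists, 99 of them higher and 17 lower. Annexins, calcium-dependent membrane-binding proteins, had 9 tested genes at 1 FPKM or more, of which 4 rose (Anxa1, Anxa2, Anxa3 and Anxa5) and 5 did not pass. Anxa2 rose from 18.9 to 75.1 FPKM. Serpinh1, a collagen chaperone, rose from 63.4 to 145 FPKM. Ctsl, the lysosomal protease cathepsin L, rose from 147 to 371 FPKM, and Pth1r, a receptor of parietal endoderm for parathyroid hormone-related protein, from 1.19 to 11.5 FPKM.

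Running medians of 41 neighbouring genes passed 0.32, the largest value in 100 shuffled gene orders, in 7 segments that held 480 expressed genes, or 3.89% of those expressed. These segments contained 7 of the 29 genes that fell (24.1%) and 2 of the 149 that rose. The falls lay in segments that were lower in the KD and the rises in segments that were higher. The segments were chosen from the same log2 folds, so these shares follow in part from that choice and are not separate evidence. On chromosome 1 the segment from 58.9 to 75.4 Mb had a ratio of 0.731 and held Fzd7, Abi2 and Rpl37a among the falls, and the segment from 153 to 158 Mb had a ratio of 1.33. On chromosome 6 the segments from 11.9 to 29.2 Mb and from 47.9 to 72.1 Mb had ratios of 1.39 and 1.29. A further segment there, near 142 Mb, held 2 expressed genes with a median of 0.13. On chromosome 14 the 14 genes between 104 and 119 Mb had a median of -0.34.

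The rise of endoderm and mesenchyme genes may come from feeder fibroblasts in the KD cultures, from differentiated cells among the ES cells, or from the control library. The KD value pools 3 clones, so a rise in a single clone cannot be told apart from a rise in all of them. Of the 25 feeder markers, 13 were expressed at 1 FPKM or more in the control and 3 belonged to another list, and no sort or gate is described. Fibroblasts carry abundant fibrillar collagen, but the median gain of Col1a1, Col1a2 and Col3a1 was 2.71 FPKM, 0.0319 of the median gain of 5 basement membrane genes (85.2 FPKM), which argues against feeder cells as the main source of those 5. Over all expressed members the collagen gain was 0.362 of the median gain of the endoderm list (7.49 FPKM) and 0.605 of that of the mesenchyme list (4.49 FPKM), between the bounds set for the test, so feeder cells stay open for the rest of both lists. With 1 control library, a property of that library cannot be told apart from an effect of the knockdown, through more endoderm-like cells or through higher expression in each cell, which remains an untested hypothesis.

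The shift of chromosome 6 could come from a copy-number difference in some clones or in the control. It could also come from the make-up of its genes, and that of chromosome 10 likewise. After subtraction of the median of genes with like GC content, length and expression, the medians were 0.25 for chromosome 6 and -0.18 for chromosome 10, which argues against such a bias for both. On chromosome 6, 87.5% of the 20 Mb windows lay above 0.1, as a copy-number difference of the whole chromosome would give, though they ranged unevenly from 0.085 to 0.39. Its median ratio of 1.20 lies near the 1.17 that 1 of 3 clones with an extra copy would give. For 2 and for 3 such clones the ratio would be 1.33 and 1.5. Segments of chromosome 6 chosen for being high had ratios of 1.39 and 1.29, so the number of clones was not settled. A loss of chromosome 6 in part of the control cells could also raise the ratio and was not tested. On chromosome 10 the share of windows below -0.1 was 28.6%, which argues against a whole-chromosome change, whereas in a segment from 69.0 to 100.1 Mb bounded with every other gene 91.3% of the 127 genes left out of that search lay below 0, against 45.3% outside, and a gain in the control (ratio 0.667) or a loss in KD clones stays open for its ratio of 0.714. The glycolysis and hypoxia list kept a median of -0.33 without chromosome 10, so that chromosome does not account for all of its shift, and no biological explanation of the shifts was tested.

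The low Y-linked levels in the control may come from loss of the Y chromosome in most of its cells, a change known in male ES cell lines. Among Y-linked genes at 5 FPKM or more in the KD, the ratios of control to KD for Eif2s3y, Ddx3y and Uty lay within a factor of 1.42 of each other, as a common loss would give. Genes below that minimum differed, with Uba1y in the control at 15.3% of its KD level of 0.486 FPKM and Kdm5d at 22.8% of 0.236 FPKM, so the test covers only those 3 genes. A chosen subclone or an exchange of the control for another culture would leave the same trace and stays open, as does regulation by the knockdown, which was not tested. The largest median of an autosome was 0.26, on chromosome 6, against log2 folds of 2.93 to 4.46 for those 3.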
